A study of Mus musculus with 12 samples.

How the data were processed

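Chromatin immunoprecipitation libraries of mouse embryonic stem cells were analysed from 1 table of 1 kb bins that holds 8 of the 12 libraries of the series. The remaining 4 libraries, V65 control and V65 Gzf1-Flag with anti-FLAG, an RGM control with anti-FLAG and a further RGM Gzf1-Flag library with anti-FLAG, were not analysed here. The planned limma comparison of anti-FLAG libraries with and without Gzf1-Flag was therefore not run, and no reads were split by allele. A planned motif comparison was not run because no genome sequence was used.

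Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to mm10 with Bowtie2 2.5.4, handled with SAMtools and binned with deepTools. The deposited values are estimated counts of reads per bin (expected counts) that the authors did not scale to depth, with a read that crosses a bin edge split between bins. This was checked on the values: 100% were multiples of 0.05, chromosome totals lay within 0.0506 of a whole number, and the share of values that were not whole differed by −1.66 to 0.393 percentage points from that of footprints of 20 bp. Filters on duplicates and mapping quality are not stated.

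Each library was divided by its mean over 2,462,755 autosomal bins. Enrichment was log2((ChIP + 0.5)/(input + 0.5)) against the single Cas9 input, which also served for RGM, and a bin counted as enriched at 2 or more. Bins with an input below 0.25 or above 3 times its mean were left out (439,998 and 65,277 bins), which kept 1,957,480 bins (79.5%). Local background was the median of the bins within 10 kb on each side. Enriched bins at most 1 kb apart were merged into regions. With 1 library per group no test between libraries was run, and counts carry 95% exact Poisson intervals, ratios of counts exact binomial (Clopper-Pearson) intervals on counts rounded to whole reads, and a count of 0 a limit of 3 reads. These cover counting error only, and sequenced reads are not independent molecules.

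Shared bins were compared with the count for independent lists and with 20 simulated draws that used the real input and a common profile. The profile was the median per bin of all ChIP libraries. Sites high in most libraries stay in it, so the draws are not free of antibody signal. Windows of 20 imprinted DMRs and 9 gene lists were compared with 10,000 random sets matched on input in 10 classes. The gene table gives no strand, so both annotated gene ends were used in place of transcription starts, a choice made after the data were seen. Knockout and control were compared at sites with 1000 sets of bins matched on the mean of both libraries in 20 classes, a comparison set up after the data were seen. The rule for named genes was to give every window of the locus list, the 15 regions per antibody with the highest value of the lower line, in each gene list up to 4 highest members and the lowest, and the 15 regions with the largest knockout difference each way; of the members of the lists those of most weight are printed. Some regions and list members that the rule names are not reported here.

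In simulated data with known sites the rule recovered 42.3%, 50.5%, 39.2% and 41.2% of 5-fold sites and 96.8%, 92.6%, 92.6% and 95.7% of 10-fold sites in Cas9 and RGM wild-type anti-GZF1 and Cas9 and RGM anti-FLAG. It called 18, 156, 22 and 16 of 2,190,234 unchanged bins, with a simulated input. With the real input and the common profile of all ChIP libraries, simulation gave 234.05, 645.75, 216.15 and 225.75 calls on average. A simulated log2 ratio of −1 between knockout and control was read as −0.54 with the pseudocount and −0.95 without it. Library depth was 10.1 to 94.2 M reads, and the median input in enriched bins was 1 or 2 reads.

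The scaling, pseudocount, filter, threshold, gene lists, windows and most alternatives were fixed before the data were examined. Chosen after the data were seen were the ranking of 6 kb windows by knockout ratio, the correction by the surrounding 1 Mb, the 84 bins that also pass a local log2 value of 1.5, the averaging of both lines for gene lists, the use of H3K27ac and the knockout as background, and the comparisons of empty bins and of line-specific bins. The alternatives tried were pseudocounts of 0.25 and 1, scaling to the median, no input filter, local background, thresholds of 1.5 and 3, bins within 1 kb counted as shared, and random lists also matched on H3K27ac in 5 classes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.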

Results

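The series mapped GZF1, a BTB zinc-finger protein that binds DNA, in mouse embryonic stem cells by chromatin immunoprecipitation and sequencing of formaldehyde-fixed, micrococcal nuclease-digested chromatin. Its title names the Dlk1-Dio3 domain, an imprinted cluster on chromosome 12 whose imprinting depends on a differentially methylated region between Dlk1 and Meg3 (the IG-DMR). Of 12 libraries in the series 8 were analysed here, each the single library of its line, genotype and antibody, so there are no replicates and no p-values. In the Cas9 line they were wild type with anti-GZF1 (60.6 M reads), a control with anti-GZF1 (94.2 M reads), the Gzf1 knockout with anti-GZF1 (85.9 M reads), Gzf1-Flag clone 35 with anti-FLAG (70.0 M reads), H3K27ac (40.8 M reads) and input (10.1 M reads). In RGM, a 129xCAST line, they were wild type with anti-GZF1 (21.8 M reads) and Gzf1-Flag clone 56 with anti-FLAG (67.0 M reads). Gzf1-Flag was overexpressed in both clones. The mean depth per autosomal 1 kb bin ran from 3.93 reads in the input and 8.61 reads in RGM wild type to 35.8 reads in the control. Read density below is relative to the autosomal mean of the same library, with 95% exact Poisson intervals that cover counting error only.

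The IG-DMR carried a strong anti-FLAG peak in both lines. The bin at chromosome 12, 109,527,001 to 109,528,000 (mm10) lies inside the long non-coding RNA gene Gm34081, between Dlk1 (109,452,485 to 109,463,336) and Meg3 (109,540,996 to 109,571,729). It held 368.5 anti-FLAG reads in Cas9, a density of 13.5 (12.2 to 14.98), and 460.35 in RGM, a density of 17.4 (15.8 to 19.04). The anti-GZF1 signal was raised in the same bin in both wild types. Its density was 2.33 (1.76 to 3.04) from 55 reads in Cas9 and 4.88 (3.52 to 6.59) from 42 reads in RGM. The bin was picked as the highest of the IG-DMR window in Cas9 wild-type anti-GZF1, so the value of that library is a selected maximum. The control with the same antibody had a density of 1.66 (1.26 to 2.13), 1.21 times local background, and H3K27ac had 0.98 (0.576 to 1.64). Against this background, the median of the bins within 10 kb on each side, the fold was 12.2 and 10.1 for anti-FLAG in Cas9 and RGM and 3.06 and 2.91 for wild-type anti-GZF1. Of 1,957,480 autosomal bins that passed the input filter, 5 in Cas9 and 7 in RGM had a higher anti-FLAG log2 value over local background, and 3572 and 12655 had a higher wild-type anti-GZF1 value. The input had 0 reads in this bin, which allows a density of up to 0.764, so its values over input depend on the pseudocount and are given no rank, and the bin itself did not pass the input filter.

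**Figure D1:**
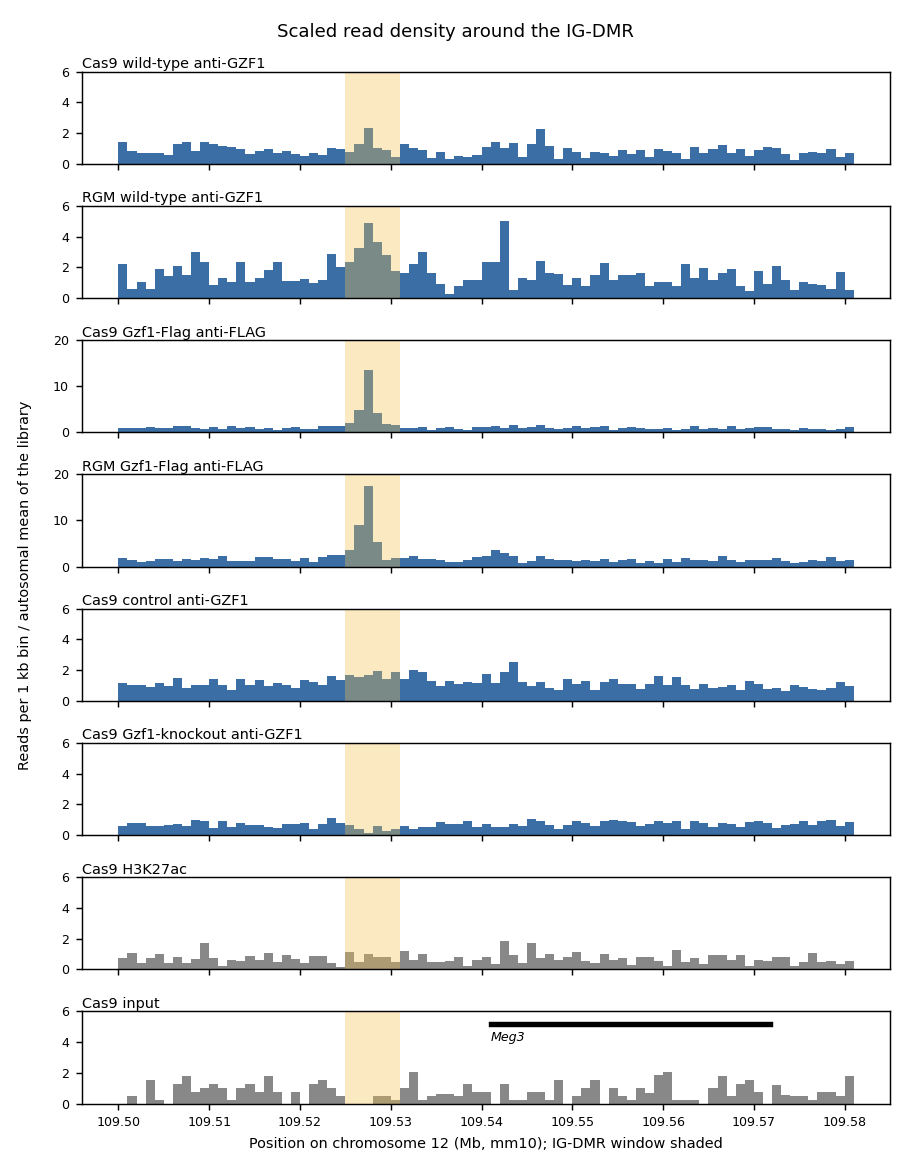
Read density per 1 kb bin, divided by the autosomal mean of each library, along chromosome 12 (mm10) around the IG-DMR, with 1 panel per library and the 6 kb IG-DMR window shaded. In the bin starting at 109,527,001 the anti-FLAG libraries reach 13.5 and 17.4, wild-type anti-GZF1 2.33 and 4.88, the control 1.66 and the knockout 0.152.

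Other parts of the domain had less anti-FLAG signal than the IG-DMR window. The Cas9 anti-FLAG density was 4.71 (4.38 to 5.06) over the 6 kb IG-DMR window, 1.26 (1.14 to 1.39) over Dlk1, which encodes a Notch-like ligand, and 1.15 (0.965 to 1.38) at the Meg3 promoter. It was 0.98 over the Meg3 body, 0.784 at Rtl1, a retrotransposon-derived gene, 0.855 and 1.02 over the non-coding RNA genes Rian and Mirg, and 1.19 (0.998 to 1.42) at Dio3, a deiodinase gene. In RGM the anti-FLAG density was 6.45 (6.06 to 6.86) over the IG-DMR window and 2.74 (2.43 to 3.07) at the Meg3 promoter, and Dio3 had 317.55 reads with a density interval of 2.68 to 3.35. RGM wild-type anti-GZF1 had 2.72 (2.21 to 3.34) at the Meg3 promoter and 3.46 (2.86 to 4.13) at Dio3, against 1.03 (0.834 to 1.25) and 1.62 (1.38 to 1.90) in Cas9 wild type.

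Across the genome the question was where anti-FLAG signal of the tagged GZF1 was shared by both lines. No anti-FLAG library without Gzf1-Flag was analysed here, so these sites cannot be separated from background of the anti-FLAG antibody by such a control. Among bins that passed the input filter, which leaves out the IG-DMR peak bin, the highest shared site lay by the ends of Pomp, a proteasome assembly factor gene, and Slc46a3 (chromosome 5, 147,874,001 to 147,875,000), with log2 values over input of 3.92 in Cas9 and 3.55 in RGM. The end of the ubiquitin ligase gene Pdzrn3 (chromosome 6, 101,378,001 to 101,379,000) had 3.43 and 3.41, and the inside of the deubiquitinase gene Usp25 (chromosome 16, 77,041,001 to 77,042,000) had 3.52 and 3.40. The neighbouring ends of Sirt4, a mitochondrial sirtuin gene, and Pxn, the paxillin gene (chromosome 5, 115,490,001 to 115,491,000), had 4.04 and 3.39. Micu2, which encodes a regulator of mitochondrial calcium uptake, had 3.73 and 3.18. Also among the 15 highest regions were Gm38832, D330050I16Rik with Tsga10ip, Gm3963 with Gm52052, and 6 positions without a gene within 5 kb, led by chromosome 4, 100,631,001 to 100,632,000 (3.71 and 3.54). Bins at a log2 value of 2 or more numbered 394 in Cas9 and 988 in RGM, of which 185 were shared and formed 160 regions. Simulated libraries with the real input and a common profile of all ChIP libraries had 216.15 and 225.75 such bins on average. That profile keeps sites high in most libraries, so the comparison cannot tell how many bins arise without signal. The counts depend strongly on the settings: with a pseudocount of 1 they were 123 and 85 with 60 shared, and with local background 145 and 123 with 69 shared. Of the regions 100 had a gene end within 5 kb, 34 lay only inside a gene and 26 had neither. Independent lists would share 0.199 bins, and the simulated libraries shared 100.1 on average (at most 113 in 20 draws). Both lines were divided by the same shallow input, so the excess over simulation is not free of its errors.

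Anti-FLAG sites were also raised with anti-GZF1 in both wild types, and little in the control or the knockout. Over the 185 bins the median log2 value over local background was 1.59 and 1.47 for anti-FLAG in Cas9 and RGM and 0.69 and 0.83 for wild-type anti-GZF1. It was 0.18 in the control, 0.14 in the knockout and 0.25 for H3K27ac. The control and the knockout differed from the other Cas9 libraries in chromosome dosage, with a chromosome X median of 0.985 in the control and 0.648 in the wild type. At the Pdzrn3 end the density was 18.7 and 18.3 with anti-FLAG, 8.45 and 13.6 with wild-type anti-GZF1, 2.34 in the control and 1.08 in the knockout.

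**Figure D2:**
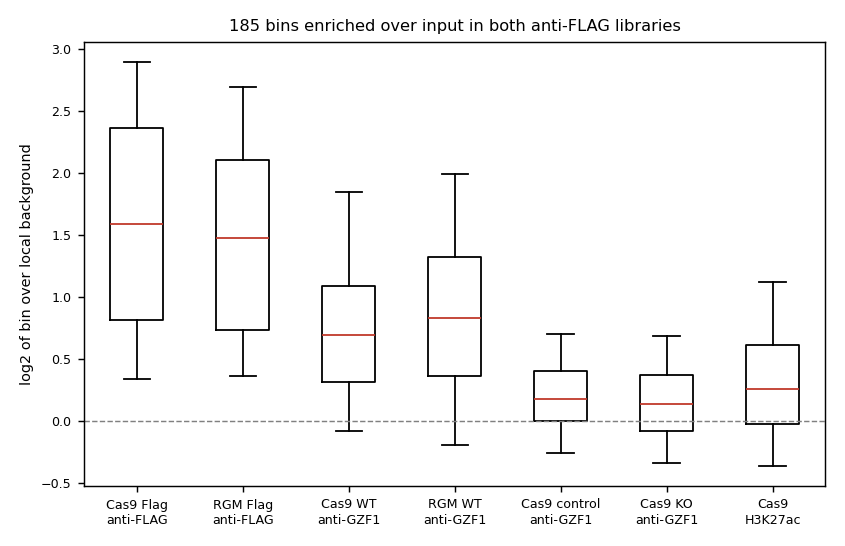
Log2 ratio of read density to local background, the median of the bins within 10 kb on each side, for the 185 bins enriched over input in both anti-FLAG libraries, with 1 box per library. Medians are 1.59 and 1.47 for anti-FLAG, 0.69 and 0.83 for wild-type anti-GZF1, 0.18 for the control, 0.14 for the knockout and 0.25 for H3K27ac.

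The bins ranked highest with anti-GZF1 itself were mostly other places. They were headed by the end of Mrpl4, a mitochondrial ribosomal protein gene (chromosome 9, 21,002,001 to 21,003,000), with log2 values of 2.83 in Cas9 and 3.33 in RGM. Next came 1700017J07Rik with Gm33622 and Gm4721 (2.82 and 3.38), Maea (2.80 and 2.92), Mus81 with Cfl1 and Snx32 (2.80 and 3.37), Sirt4 with Pxn (2.69 and 3.08), the isoprenoid pathway gene Idi1 (2.66 and 3.04) and Vsig10l (2.61 and 2.97). Acbd3, Olfml2b, Tulp3, Sptlc1, Adcy8, Dnah6, Gm34213 and Glis2 completed the 15. Enriched bins numbered 609 in Cas9 and 3581 in RGM, with 315 shared in 313 regions, against 1.11 for independent lists and 103.85 on average in simulation. Simulation gave 234.05 and 645.75 bins per library, and with the same antibody the control had 439 enriched bins and the Gzf1 knockout 522. The median input in the 15 regions was 1 read, and 0 of them stayed at the threshold against local background, where 11 of the 15 anti-FLAG regions did. Bins enriched with both antibodies numbered 87 in Cas9 and 531 in RGM. Simulation gave 98.3 and 102.95 on average. Its common profile keeps sites high in most ChIP libraries, so it cannot show whether the antibodies share more bins than without signal.

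Imprinted differentially methylated regions were compared as a set because the study concerns imprinting. The 20 windows stood high in every ChIP library, including the knockout and H3K27ac. Their median log2 value over input was 0.29 and 0.37 in Cas9 and RGM wild-type anti-GZF1, 0.18 and 0.13 in Cas9 and RGM anti-FLAG, 0.18 for H3K27ac, −0.19 in the control and −0.20 in the knockout. Among 10,000 random sets matched on input each of these 7 medians was at percentile 99.82 or higher. The IG-DMR was the only window at 1 or more with anti-FLAG, at 2.87 in Cas9 and 3.29 in RGM. The Zrsr1 DMR followed in Cas9 at 0.98. This gap depends on the input, with a density of 0.212 from 5 reads in the IG-DMR window and 2.23 in the Zrsr1 window. The anti-FLAG density of the IG-DMR and Zrsr1 windows was 4.71 and 4.87 in Cas9 and 6.45 and 3.71 in RGM. In Cas9 this was 4.27 and 2.63 times local background. The control reached a log2 value over input of 1.62 in the IG-DMR window. The Zrsr1 bin at chromosome 11, 22,972,001 to 22,973,000 had 6.01 and 3.56 times local background with anti-FLAG in Cas9 and RGM, 1.39 times in the knockout and 2.16 times for H3K27ac. In the Grb10 DMR (chromosome 11, 12,026,001 to 12,027,000) wild-type anti-GZF1 reached 5.22 times local background in Cas9 and 9.97 times in RGM, against 1.06 times in the control and 1.22 times for H3K27ac. The input itself was at 3.08 times there, so the log2 value over input was 0.81 in Cas9 and 1.53 in RGM wild type. Anti-FLAG was at 2.75 and 3.72 times local background in that bin in Cas9 and RGM, with log2 values over input of −0.32 and 0.33. The named bins of these windows are those highest in Cas9 wild-type anti-GZF1, so the values of that library there are selected maxima. Cas9 anti-FLAG log2 values were −0.10 at the H19-Igf2 control region, 0.13 at Kcnq1ot1, 0.22 at Peg3 and 0.60 at Snrpn.

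Gene lists were compared at annotated gene ends, with both lines averaged per antibody, against 10,000 random lists matched on input. Pluripotency genes had medians of 0.60 for anti-GZF1 and 0.40 for anti-FLAG (percentiles 99.25 and 98.9). Lin28a, which encodes an RNA-binding protein that blocks let-7, was their highest at 1.04 and 0.95 and Esrrb the lowest at −0.05 and −0.14, and against local background the percentiles were 17.05 and 32.9. Genes of GDNF and RET signalling, which acts in kidney and neural development, had medians of 0.66 and 0.48 (percentiles 99.1 and 99.4). The receptor gene Ret had 1.07 and 0.90 and Spry1, an inhibitor of the pathway, 1.00 and 0.89, and the anti-GZF1 percentile was 87.7 against local background and 93.5 when matched on H3K27ac as well. Imprinted genes had 0.54 and 0.39 (percentiles 97.5 and 97.1), with Ndn at 1.42 and 1.04, Meg3 at 0.94 and 1.21 and Peg13 lowest at −0.32 and −0.19. Matched on H3K27ac as well, their percentiles were 91.5 and 93.5.

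The remaining lists were closer to random ones or as high for H3K27ac. Methylation and imprint maintenance genes were at percentiles 94.96 for anti-GZF1, 98.2 for anti-FLAG and 98.9 for H3K27ac, with Tet2 at 1.23 and 0.89 and the histone methyltransferase gene Setdb1 at 1.51 for anti-FLAG, and the anti-FLAG percentile was 35.4 against local background. Germline genes with methylated promoters were at 78.9, 92.4 and 98.4, led by Hormad1 at 1.29 for anti-GZF1, and against local background at 98.67 for anti-GZF1 and 98.16 for anti-FLAG. Bivalent developmental genes were at 86.9, 62.1 and 35.8. Ribosomal protein genes were at 84.4, 18.7 and 71.5, fibroblast feeder genes at 28.7, 51.7 and 67.6, and differentiated tissue genes at 25.7, 53.7 and 57.2.

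H3K27ac, a mark of active promoters and enhancers, was compared with GZF1 in Cas9. At gene ends the median H3K27ac log2 value was 0.26 for ribosomal protein genes and 0.34 for pluripotency genes. It was 0.32 for differentiated tissue genes and 0.27 for all genes. The library thus hardly set these lists apart, and a low value in it does not show that the mark is absent. Of the anti-GZF1 bins 148 (24.3%) and of the anti-FLAG bins 61 (15.5%) were among the 632 bins enriched for H3K27ac. Simulation gave 107 and 104.75 shared bins on average, and independent lists 0.197 and 0.127. The simulated profile holds sites high in most ChIP libraries, so no conclusion is drawn from the comparison with simulation. The shared counts were 0 and 0 with a pseudocount of 1, 9 and 9 with local background, and 2098 and 1503 with a pseudocount of 0.25. Spearman's rho across 1,957,480 bins, which are not independent replicates, was 0.761 with anti-GZF1 and 0.77 with anti-FLAG. With each library set against local background it was 0.22 and 0.219. The values over input share the same input, with a mean of 3.93 reads per bin, as denominator. This alone raises rho, by an amount that was not measured.

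The knockout comparison asks which anti-GZF1 signal depends on Gzf1. Over the targeted gene (chromosome 2, 148,679,384 to 148,692,949) the read density was 0.688 in the knockout, 0.903 in the control, 1.61 and 1.75 in Cas9 and RGM wild-type anti-GZF1, 1.60 and 1.93 in Cas9 and RGM anti-FLAG, 2.07 for H3K27ac and 1.47 in the input. The ratio of knockout to control there was 0.762 (95% exact binomial interval 0.658 to 0.881), and 1.00 (0.866 to 1.16) relative to the surrounding 1 Mb. Reads in 1 kb bins cannot show a small edit, and they do not measure GZF1 protein.

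At the IG-DMR the knockout had far fewer anti-GZF1 reads than the control. The 6 kb window held 81.15 knockout and 363.65 control reads, a ratio of 0.242 (0.188 to 0.308), or 0.302 (0.234 to 0.385) relative to the surrounding 1 Mb. The peak bin held 5 and 59.4 reads, a ratio of 0.092 (0.0288 to 0.227). The control had no clear peak in this bin, at 1.21 times local background, and the knockout was at 0.237 times. Among 2,394,163 overlapping 6 kb windows with 100 or more control reads, 0 windows elsewhere had a log2 ratio with the pseudocount of 0.5 as low as the −1.27 of the IG-DMR (−2.04 without the pseudocount), and the lowest was −0.96 (chromosome 4, 107,290,001 to 107,296,000). In the rest of the domain the ratio was 0.396 (0.301 to 0.517) at the Meg3 promoter, 0.683 (0.622 to 0.750) over the Meg3 body, 0.785 (0.686 to 0.898) at Dlk1, 0.729 (0.626 to 0.849) at Rtl1, 0.738 (0.695 to 0.783) at Rian, 0.738 (0.654 to 0.832) at Mirg and 0.978 (0.775 to 1.23) at Dio3. Relative to the surrounding 1 Mb, whose ratio was 0.801, it was 0.495 (0.376 to 0.645) at the Meg3 promoter, 0.852 (0.776 to 0.936) over the Meg3 body and 0.921 (0.868 to 0.977) at Rian. The corrected intervals held 1 at Dlk1 (0.857 to 1.12), Rtl1 (0.781 to 1.06), Mirg (0.816 to 1.04) and Dio3 (0.967 to 1.54).

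**Figure D3:**
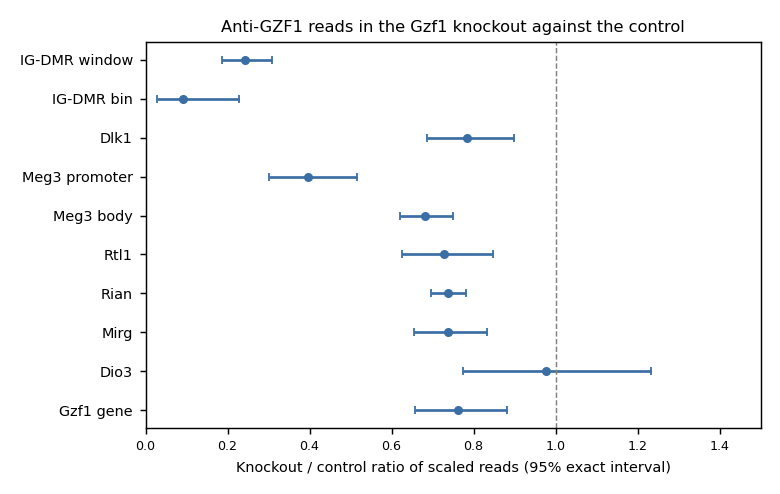
Ratio of scaled anti-GZF1 reads in the Gzf1 knockout to those in the control at windows of the Dlk1-Dio3 domain and over the Gzf1 gene, 1 library each, with 95% exact binomial intervals as bars. The IG-DMR window is at 0.242 and its peak bin at 0.092, and Dlk1, Rtl1, Rian and Mirg lie between 0.729 and 0.785.

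Anti-FLAG sites as a set were slightly lower in the knockout than in the control. The median log2 ratio over the 185 bins was −0.06, with 108 bins lower in the knockout, at percentile 1.7 of 1000 bin sets matched on signal (medians from −0.08 to 0.09). Over the 84 of these bins that also passed a local log2 value of 1.5, a subset chosen after the data were seen, it was −0.124, at percentile 0 of matched sets whose lowest median was −0.121. The control itself had little signal to lose: its median log2 value over local background in the 185 bins was 0.18, against 0.69 in Cas9 wild type. A small difference from the knockout therefore does not show that these sites are independent of Gzf1. Of the 160 anti-FLAG regions 20 had an interval wholly below a ratio of 1 and 11 wholly above it. Of the 313 anti-GZF1 regions 23 were below and 28 above. After correction by the median ratio of the chromosome, 18 anti-FLAG regions were below and 8 above, and 17 anti-GZF1 regions were below and 31 above. The lowest was inside Cald1, the caldesmon gene (chromosome 6, 34,709,001 to 34,710,000), with 25.4 knockout and 122.55 control reads, a ratio of 0.221 (0.138 to 0.341). Among the next were the IG-DMR bin starting at 109,528,001 at 0.299 (0.170 to 0.503), the netrin gene Ntn4 at 0.326 (0.181 to 0.559) and Pdzrn3 at 0.465 (0.306 to 0.696). The 15 lowest also included Gm31759, 9130230L23Rik, Gm33434, Col13a1, Bri3, Gm34213, Prokr2, Nfib and 2 positions without a gene. The highest was the end of Rps10, a ribosomal protein gene, at 2.25 (1.41 to 3.67), followed by Pcdha2 at 2.47 (1.39 to 4.58), Fcgbp at 2.17 (1.37 to 3.52), Cnih3 at 2.21 (1.36 to 3.69) and Rims4 at 2.61 (1.39 to 5.12) in order of the log2 ratio with its pseudocount. Arhgef10, Mib1, Znrf1, Hmox1, Cc2d2b, Slc17a5, Tnxb, Hmgn2, Tnpo2 and 1 position without a gene completed the 15 highest. Chromosome dosage differed too, with median knockout to control ratios of 1.21, 1.24 and 1.29 on chromosomes 8, 18 and 19 and 0.861 and 0.852 on chromosomes 4 and 6. Of the 15 lowest and the 15 highest regions, 8 and 7 lay on chromosomes shifted the same way by more than 10%.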

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

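All tests in this part were chosen, and their outcomes stated, only after the values they bear on had been seen. In the IG-DMR bin at chromosome 12, 109,527,001 to 109,528,000 the log2 value over local background was 0.20 in the control and −0.81 in the knockout. The single control library and the single knockout library lay on opposite sides of 0, and the difference was not tested between replicates because there are none.

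The lower anti-GZF1 signal of the knockout at the IG-DMR was weighed against technical causes. A copy number change of the whole region was argued against, since the flanks, 20 kb on each side, had a log2 ratio higher than the window by 0.8647 with a counting error of 0.347. The flanks were low themselves, at a ratio of 0.651 (0.601 to 0.704), or 0.812 (0.750 to 0.879) relative to the surrounding 1 Mb. The lower signal was thus not confined to the window. A lower recovery of imprinted DMRs in general was argued against, since the median log2 ratio of the other 19 windows was 0.0004 with a bootstrap SD of 0.0625. A focal deletion stays open, because the ratio relative to the surrounding 1 Mb was 0.3016, below that of 1 lost copy, and a loss of both copies in part of the cells could give it. A difference in pull-down between single libraries and a dependence of the signal on Gzf1, which the genotypes name, also stay open. In the peak bin the control had little signal above local background to lose, at 1.21 times. The knockout was below its local background, at 0.237 times. A loss of the control's signal above background would thus not alone give the whole drop.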

How the results depend on the processing

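The alternatives here were planned, except the restriction to the 84 bins, local scaling of knockout and control, the surrounding 1 Mb, leaving out the IG-DMR window, and the other settings of the IG-DMR ratio, which were chosen after seeing the data. Counts follow the order Cas9 wild-type anti-GZF1, RGM wild-type anti-GZF1, control, knockout, Cas9 anti-FLAG, RGM anti-FLAG and H3K27ac, then bins shared by lines for anti-GZF1 and anti-FLAG, bins shared by antibodies in Cas9 and RGM, and bins shared by H3K27ac with anti-GZF1 and anti-FLAG.

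With a pseudocount of 0.25 the counts were 5990, 14790, 2306, 2448, 4200, 7749 and 6460, then 2629 and 1622, 1801 and 3814, and 2098 and 1503. With a pseudocount of 1 they were 14, 414, 121, 171, 123, 85 and 17, then 11 and 60, 4 and 27, and 0 and 0. Without the input filter they were 11739, 28163, 12855, 13864, 10543, 16132 and 15650, then 5014 and 3989, 4181 and 7450, and 4584 and 3983. Against local background they were 46, 1222, 55, 64, 145, 123 and 80, then 28 and 69, 16 and 44, and 9 and 9. At a threshold of 1.5 they were 11101, 26327, 4419, 4837, 7795, 14029 and 12761, then 4875 and 3114, 3486 and 6964, and 4151 and 3023. At a threshold of 3 they were 0, 31, 44, 53, 35, 19 and 0, then 0 and 15, 0 and 2, and 0 and 0. Thresholds change counts by construction, and for the other settings the cause was not tested. Counts within 1.5 times those reported were given by median scaling and, for shared bins, by counting bins within 1 kb as shared.

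The percentile of the IG-DMR bin stayed at 99.35 or above in both anti-FLAG and both wild-type anti-GZF1 libraries under every alternative run, where values over an input of 0 reads give no exact rank. Against local background it was 80.67 in the control, 0.1362 in the knockout and 82.76 for H3K27ac, where it was 98.63 with a pseudocount of 1 and 96.58 without the input filter. The DMR set stayed at percentile 99.78 or above in all 7 libraries under the alternatives run. The rank correlation across bins with H3K27ac was 0.824 for anti-GZF1 and 0.832 for anti-FLAG without the input filter, and 0.2199 and 0.2191 with local background. The cause was not tested.

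Among gene lists, with local background the percentiles of pluripotency genes were 17.05 for anti-GZF1 and 32.945 for anti-FLAG, of methylation genes 35.4 for anti-FLAG, of germline genes 98.67 and 98.16, and of GDNF and RET genes 87.69 for anti-GZF1. Matched on H3K27ac as well, imprinted genes were at 91.495 and 93.485, GDNF and RET genes at 93.48 for anti-GZF1 and ribosomal protein genes at 3.52 for anti-FLAG. Methylation genes with anti-GZF1 were at 96.47 and 95.775 with pseudocounts of 0.25 and 1 and at 95.21 with median scaling. The cause was not tested.

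The log2 ratio of knockout to control at the IG-DMR window was −1.27 as reported and −2.0447 without a pseudocount, since the pseudocount pulls ratios toward 0. It was −1.26 with median scaling and −0.93 with a pseudocount of 1. Relative to the surrounding 1 Mb it was −1.07 with the pseudocount kept, whereas the ratio of 0.302 given for this comparison has no pseudocount. Over anti-FLAG bins the median ranged from −0.14 with a pseudocount of 1 (60 bins) to −0.05 over local background. Of all results under alternatives 319 kept their call or size, 83 moved, 36 no longer passed a threshold, 7 newly passed one and 0 changed sign. The motif and limma alternatives were not run. A comparison of the antibodies paired by line was not run. Depth limits the enrichment over input, since the input mean was 3.93 reads per bin.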

Other observations

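All tests in this part were chosen only after the results were seen. The imprinted DMR windows were high in every ChIP library, which may reflect a general recovery of these windows. For anti-FLAG in Cas9 this fits the values. The median difference from H3K27ac over 19 windows without the IG-DMR was at percentile 35.26 of matched random sets, and that from the knockout at 91.05. The control minus the knockout was at 42.48. H3K27ac itself marks active promoters, so it is not a neutral measure of recovery. For wild-type anti-GZF1 in Cas9 the differences from H3K27ac and from the knockout were higher, at percentiles 97.44 and 99.15. The control, with the same antibody, was not set apart from the knockout. The difference of the wild type from the knockout may therefore reflect other differences between these libraries. Whether a general recovery accounts for the wild-type values cannot be decided from them. No biological explanation was tested for the set.

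The 84 bins enriched with anti-FLAG over input and over local background had 2.54 times local background in Cas9 wild-type anti-GZF1 and 1.18 times in the control. Reads carried over from the anti-FLAG library could raise the wild type. In Cas9 carry-over as the only source was argued against, since the reads spread 2.3532 times as much about a constant share as background bins do (bootstrap interval 1.67 to 3.17, limit 1.5). In RGM the same ratio was 1.7962 (1.24 to 2.43), which leaves it open. An earlier estimate of the background spread from a random part of the bins had put that lower bound on either side of the limit. Carry-over on top of other signal was not tested in either line. Chromatin recovered more in any library was argued against, since the higher of the H3K27ac and knockout median log2 values over local background was 21.467% of the wild-type log2 value. Dilution of the control by reads in bins that are empty in the other Cas9 libraries was argued against, since they held 1.3543% of its reads. A weaker pull-down, separate processing or a different stock of cells for the control and knockout stays open.

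The control and knockout libraries differed from the other Cas9 libraries in where reads were placed and in chromosome dosage. Of 108,311 autosomal bins without reads in 4 other Cas9 libraries, 38.4% held reads in each of the control and the knockout, and 0.97% and 2.23% did in RGM wild-type anti-GZF1 and RGM anti-FLAG. At chromosome 9, 3,000,001 to 3,036,000 the density was 44.0 in the control and 49.7 in the knockout, against 1.66 to 3.63 in the other 6 libraries. At chromosome 17, 6,400,001 to 6,600,000 it was 0.575 in each of them, 0.467 and 0.482 in RGM, and 0.0318 to 0.0424 in the other Cas9 libraries. The median dosage of chromosome X was 0.985 in the control, 0.844 in the knockout and 0.615 to 0.669 in the other Cas9 libraries. Cas9 wild type and control had 0.787 and 1.11 on chromosome 12 and 1.13 and 0.857 on chromosome 17. Of the 439 enriched bins of the control 383 (87.2%) were enriched in the knockout too.

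At some positions both RGM libraries differed from all Cas9 libraries. Over the Skint cluster (chromosome 4, 112,000,001 to 114,000,000) the density was 0.171 and 0.101 in RGM and 0.674 to 0.738 in the Cas9 libraries. Bins at Ubqln1 (chromosome 13, 58,177,001 to 58,178,000) and Cers5 (chromosome 15, 99,735,001 to 99,736,000) had densities of 30.4 and 39.6 in RGM wild-type anti-GZF1, against 1.62 and 1.82 in Cas9 wild type.

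Bins outside the main comparisons were counted as well. Among autosomal bins left out for low input 6 had a log2 value of 2 or more over local background in both anti-FLAG libraries. In both control and knockout 23 did. Among 111,527 chromosome X bins 6 and 17 were enriched over input. The control and knockout hold reads in bins empty in other Cas9 libraries and have a higher chromosome X dosage. They are thus not a neutral measure, and the counts cannot show whether anti-FLAG bins exceed background. The 6 autosomal bins, named after their values were seen, were the IG-DMR bin, those at Gnal, Prkar2b, Mast4 and Kcnc2 and 1 position without a gene. All 6 were lower in the knockout than in the control, with a median log2 ratio of −0.49.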
